A study of Mus musculus with 48 samples.

How the data were processed

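Liver RNA from 48 female C57BL/6J mice was measured, 25 labelled WT and 23 labelled KO for Bmal1 (gene symbol Arntl) in adipocytes, collected at 6 times of day, ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. Per the labels' protocols, mice spent 1 day in constant darkness and were fasted for 24 h before collection, libraries were made from polyA RNA with a stranded TruSeq mRNA kit and 13 PCR cycles, and library construction took 3 days. The labels do not say which library was made on which day. Per the submitters' processing notes, reads were handled with CASAVA (no version given) and STAR 2.4.1d on mouse genome build mm9. The deposited values are read counts per gene and sample, whole numbers for 22354 genes with Ensembl identifiers, symbols and mm9 coordinates, per the file headers, and the file's name says that they are counts on the sense strand. The counting program, the annotation release and any step that equalised depth are not stated in the labels or the headers.

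Without Alb, the gene of serum albumin, the counts of a library summed to between 12.8e6 and 13.0e6 (median 12.9e6), a spread so narrow that the libraries look brought to about the same depth before deposit. The Alb values were not plain counts: they were whole multiples of a fixed step of 1311.614 reads, within 0.00094 of a step, and made up 5.66% to 14.6% of all counts. Alb was therefore left out of library sizes and tests, a choice made after the values were seen, and no value is given for it. The symbol of 95 genes occurred on more than 1 line of the table, and these lines were kept apart by their identifiers.

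Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, which left 13644 genes, and libraries were scaled by TMM (factors 0.892 to 1.11). A negative binomial quasi-likelihood model with 12 group means (genotype by time) gave the KO minus WT difference as the mean over the 6 times, the difference at each time, and the interaction of genotype with time (5 degrees of freedom). Rhythms were tested in a second model with a mean, a 24 h cosine and a 24 h sine term per genotype, which gave a test in WT, a test in KO and a test of the difference (each with 2 degrees of freedom). The p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Log2 fold changes are KO minus WT with a standard error (SE). Levels are CPM (edgeR counts scaled to a common library size) with the standard deviation (SD) between mice, computed with the scaled library sizes. Amplitude is the distance from the mean to the peak of the fitted cosine on log2 CPM (prior count 2), and its SE comes from least squares. For the ratio of KO to WT amplitude, genes were chosen in a fit with a cosine shared by both genotypes (adjusted p under 0.01, amplitude at least 0.25), and the median was set against 100 random exchanges of genotype labels within times. Tests of body weight, age and GC slope exchanged genotype labels within times (100000 draws, two-sided).

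Gene lists were fixed together with the design and tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists; results with an estimated correlation and with fry stand beside it. The 19 gene groups were core clock; fatty acid and triglyceride synthesis; cholesterol synthesis and uptake; PPARalpha targets, fatty acid oxidation and ketogenesis; lipid droplet and steatosis; gluconeogenesis; glycolysis and glycogen; insulin and growth hormone responsive; bile acid synthesis and transport; xenobiotic metabolism; female-biased liver; male-biased liver; acute phase; unfolded protein and integrated stress response; heat shock and temperature responsive; glucocorticoid responsive; immediate early; NRF2 and oxidative stress; and cell cycle. The 10 cell type lists were adipocyte, Kupffer cell and macrophage, T, NK and B lymphocyte, neutrophil, stellate cell and fibroblast, sinusoidal endothelium, cholangiocyte, exocrine pancreas, erythroid and hepatocyte. Of 445 list entries, 436 were found by symbol, 6 by identifier under an older symbol, and 3 were not found. The enrichment of rhythmic genes in each list was tested with Fisher's exact test against all tested genes, which takes genes as independent.

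The genes named were set by a rule: Arntl in every group; the 10 higher and 10 lower genes with the largest log2 fold change over all times among those past the threshold with a mean log2 CPM of at least 0; the 3 higher and 3 lower at each time by the same criteria; the 10 genes with the smallest p past the threshold for the interaction and for the difference in rhythm; every core clock gene and the 10 genes with the largest WT amplitude and a mean log2 CPM of at least 2; and for each list the up to 4 members with the smallest p among those past the threshold, or, where none passed, the member with the smallest p. The groups, the tests, this rule, the lists and most alternatives were chosen before the data were examined. The alternatives were size factors of DESeq2, no filter, DESeq2 1.42.0 and limma voom as tests, age and body weight as covariates, the replicate number within a time as a block, collection time as a factor, equal numbers per time, other settings of the amplitude ratio, and leaving out each library in turn. Alternatives chosen after seeing the data were Alb kept, the GC content trend of each library removed, leaving out 7 libraries of extreme GC slope, and a permutation test of list means.

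GC content of genes was taken by Ensembl identifier from the GENCODE M21 annotation (97.6% of tested genes), and no coordinate of that annotation was used. The GC slope of a library is the slope of its log2 CPM, less the mean over libraries, on GC content. The models were tested on simulated counts with 200 changed genes drawn from the real means, dispersions and library sizes, or 400 for rhythms. Changed genes were taken from those with a mean log2 CPM above 0. Genes were simulated independently, without the GC content trend of the real libraries, so the shares below need not hold in the real data. Over all times 72% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1 were recovered, with 4.5% false calls. At ZT8 the shares were 53% for a change of 1 and 89% for a change of 2, and for the interaction 19% and 68% of the same genes. For rhythms, 58.5% of WT amplitudes of 0.5 and 95% of amplitudes of 1 were recovered, 21.5% and 75.5% of KO amplitudes of 0.35 and 0.7, and 38% and 78% of the 100 genes with a shifted and weaker KO rhythm. A simulated amplitude ratio of -0.515 on the log2 scale was estimated as -0.511. Figures were drawn with Python 3.11.15.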

Results

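Liver transcripts were counted in 48 female C57BL/6J mice, 25 WT and 23 with a knockout of Bmal1 (symbol Arntl), a core activator of the circadian clock, in adipocytes only. Livers were taken every 4 h over a 24 h cycle at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, after a day of darkness and a fast. Each genotype had 4 mice per time, except at ZT16 with 5 WT and 3 KO mice. Each library held 12.8e6 to 13.0e6 counts without Alb (median 12.9e6), and 13644 of 22354 genes had enough counts to be tested. KO mice weighed 24.2 ± 3.57 g (SD, n = 23) and WT mice 21.8 ± 1.997 g (SD, n = 25). KO mice were heavier at 5 of 6 times, by 2.29 g on average (permutation test, two-sided p = 0.00011). Age ranged from 28.75 to 105 weeks. Mean age was the same in both genotypes at each time but ZT16 (73.4 weeks in WT, 60.3 in KO). The permutation test of age (p = 0.673) could therefore say little. Mice collected at ZT20 averaged 42.1 weeks in both genotypes. Libraries of a group correlated with r of 0.905 to 0.986 across genes (median 0.971, log2 CPM), genes not being independent replicates. The libraries differed in how abundance followed the GC content of genes, with slopes of -0.80 to 0.61 log2 units per 10 points of GC content. The slope was lower in KO by a mean of -0.18 (permutation p = 0.112). The first principal component within groups, 36.5% of the variance, had gene loadings that correlated with GC content (r = 0.75 across genes with a mean log2 CPM above 2).

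Arntl (mm9 chromosome 7, 120350979 to 120457636), the targeted gene, was present and rhythmic in the liver of both genotypes. In WT its mean level was 37.01 ± 5.93 CPM at ZT0, 21.1 ± 9.29 at ZT4, 2.14 ± 0.712 at ZT8, 2.01 ± 1.12 at ZT12, 16.2 ± 2.92 at ZT16 and 32.3 ± 3.65 at ZT20 (SD, n = 4, n = 5 at ZT16). In KO it was 32.4 ± 4.01 CPM at ZT0, 9.53 ± 2.75 at ZT4, 3.68 ± 2.14 at ZT8, 6.34 ± 5.15 at ZT12, 26.3 ± 8.74 at ZT16 and 32.1 ± 3.49 at ZT20 (SD, n = 4, n = 3 at ZT16). Over all times the log2 difference was 0.30 (SE 0.16, adjusted p = 0.347, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Liver is not the tissue in which the gene was deleted, so these values do not check the genotype labels.

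The first question was which liver genes differed between genotypes over the whole day. Dusp1 fell in KO. This gene of a phosphatase that switches off MAP kinases averaged 25.8 ± 15.3 CPM in KO (SD, n = 23) against 78.1 ± 34.3 in WT (n = 25). The AP-1 subunits Fos, Jun and Junb fell with it. Cd36, which takes up fatty acids, rose from 275 ± 108 to 456 ± 152 CPM. The insulin receptor substrate Irs1 rose from 37.1 ± 8.38 to 47.99 ± 7.68 CPM. Npas2, a relative of Clock that pairs with Bmal1, rose by 1.67 on the log2 scale (SE 0.27). Its rise came largely from ZT8, ZT12 and ZT16, where WT levels were near the floor, and at ZT4 its mean was lower in KO. Gm129 (also called Ciart), a repressor of Bmal1 activity, fell by 1.28 (SE 0.28). In all, 193 genes passed, 85 higher and 108 lower in KO. Counting these, 2333 genes had an unadjusted p under 0.05.

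Among the 10 highest genes in KO, Serpinb1a, an inhibitor of neutrophil proteases (mm9 chromosome 13, 32933961 to 32943054), rose from 34.1 ± 22.7 to 117 ± 97.4 CPM, a log2 fold change of 1.73 (SE 0.29, adjusted p = 0.000662, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and was higher at 6 of 6 times, though by only 0.29 at ZT20 (SE 0.70). The major urinary protein genes Mup17, Mup15, Mup12 and Mup16 rose by 1.89, 1.78, 1.59 and 1.22 on the log2 scale (SE 0.44, 0.45, 0.39 and 0.32), and Gm16002, which lies among them on chromosome 4, rose by 2.49 (SE 0.34). The drug-metabolising genes Cyp3a16 (2.52, SE 0.59) and Ugt2b37 (1.15, SE 0.26) and the interferon-inducible Gbp10 (1.16, SE 0.25) rose as well. These genes, Serpinb1a included, belong to multigene families or, for Gm16002, lie among one. How reads that match several members were counted is not stated and sharing of reads was not measured, so which member of each family rose is uncertain. Cyp3a16 varied widely between mice, 17.1 ± 55.7 CPM in WT and 55.1 ± 120 in KO.

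Among the 10 lowest genes in KO, Dusp1 (mm9 chromosome 17, 26642535 to 26645464) fell by 1.64 on the log2 scale (SE 0.18, adjusted p = 1.7e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and was lower at 6 of 6 times. Fos (mm9 chromosome 12, 86814840 to 86818223) fell by 1.98 (SE 0.26, adjusted p = 4.8e-06, same test), from 3.47 ± 3.03 to 0.847 ± 0.744 CPM. Its log2 difference was -2.78 to -2.08 at the other times but -0.06 at ZT16 (SE 0.61), and that of Junb was -0.04 at ZT16 (SE 0.46). Jun fell by 1.19 (SE 0.23) and the stress-inducible Gadd45g by 1.34 (SE 0.34). Aim1l fell by 2.10 (SE 0.26), from 3.40 to 0.773 CPM, and Rec8, a cohesin subunit of meiosis, by 1.82 (SE 0.22), from 1.94 to 0.563 CPM. Serpine2, an extracellular protease inhibitor, fell by 1.27 (SE 0.22), and Podn, a proteoglycan of the extracellular matrix, by 1.25 (SE 0.22). The immunoglobulin heavy chain gene Ighm fell by 1.63 (SE 0.44), from 71.1 ± 240 to 8.99 ± 3.87 CPM, but was lower at 4 of 6 times only (-5.19 at ZT16, 0.02 at ZT4 and 0.14 at ZT20). The Ighm call was lost on leaving out any of 34 of the 48 libraries, and its log2 difference was -0.98 without WT ZT16 replicate 5 and -1.04 without WT ZT12 replicate 3 (adjusted p = 0.119 and 0.167, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

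With body weight as a covariate, 37 of the 193 genes still passed (9 higher, 28 lower). Of the 20 genes above, Cyp3a16, Mup17, Mup15, Mup12, Mup16, Serpinb1a, Gbp10, Ugt2b37, Gadd45g, Gm129 and Serpine2 no longer did. Nor did Cd36, Irs1, Bhlhe40 or Vnn1. Weight itself differed between genotypes, so a call lost in this fit does not show that weight rather than genotype lay behind it. DESeq2 called 354 genes and edgeR without the count filter 122. The count was 476 without KO ZT4 replicate 1, 384 without WT ZT16 replicate 2, 368, 330 and 101 without KO ZT16 replicates 2, 1 and 3, and 125 without KO ZT4 replicate 3. Calls lost on leaving out each library were Mup16 for 28 of 48 and Mup12 for 3 (most of all KO ZT16 replicate 3), Gadd45g for 5 (WT ZT4 replicate 2), Mup15 for 4 (KO ZT0 replicate 1) and Cyp3a16 for 1 (KO ZT20 replicate 2).

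**Figure D1:**
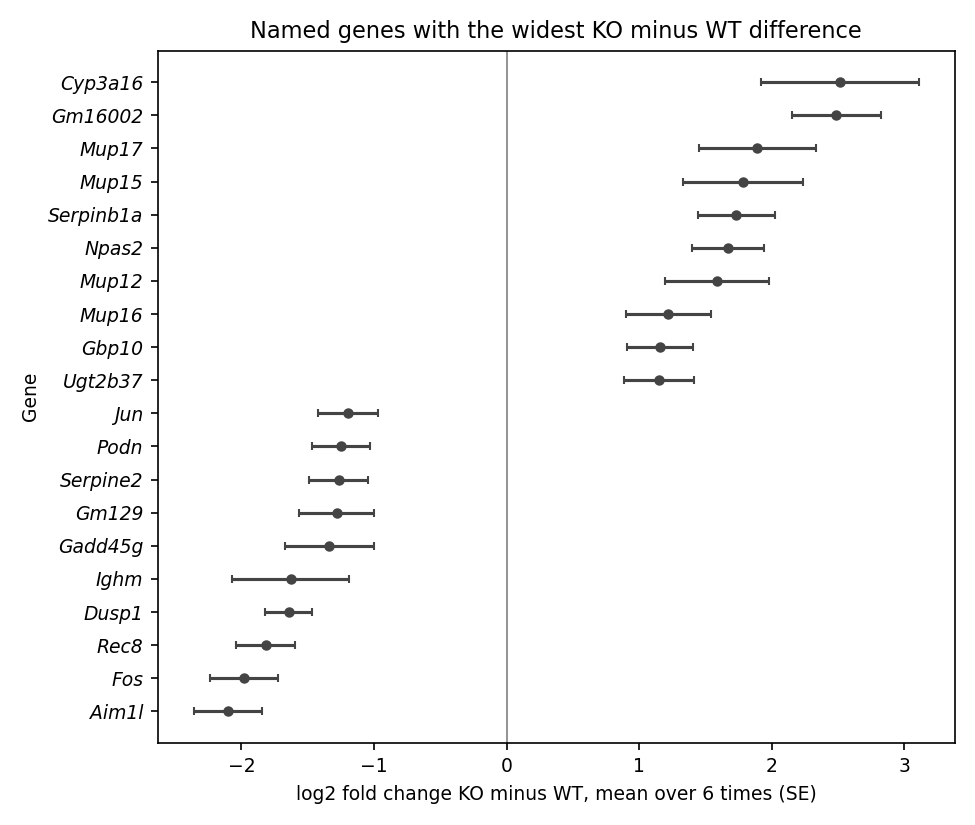
Log2 fold change, KO minus WT as the mean over 6 times, of the 10 highest and 10 lowest named genes; points are edgeR estimates and bars are SE. Estimates ran from -2.10 (Aim1l) to 2.52 (Cyp3a16).

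Immediate early genes, which are switched on within minutes of a stimulus, fell as a group in KO. At ZT16 the list mean differed by only -0.08, with KO ZT16 replicate 2 at 1.16 above the average of all mice. Markers of neutrophils and portal fibroblasts had medians below 0 too (-1.55 and -0.52), and a lower share of these cells stays open. The neutrophil list passed neither camera nor the permutation test of list means (Benjamini-Hochberg adjusted p = 0.136 and 0.450). The portal fibroblast list was written after called genes had been seen, so it is not independent of the result. Of 11 measured immediate early genes, 5 fell over all genes tested and 7 adjusted over the list alone, none rose, and 6 did not pass over all genes. Fos and Jun were joined by Junb, which fell by 1.15 on the log2 scale (SE 0.19), and by Zfp36, which fell by 1.04 (SE 0.21) and encodes a protein that destabilises short-lived mRNAs. The group's median log2 difference was -0.82 (camera, Benjamini-Hochberg adjusted p = 2.5e-08; adjusted p = 0.0474 with an estimated correlation). Of glucocorticoid responsive genes, 2 of 13 fell over all genes, Dusp1 and Fkbp5, a co-chaperone of the glucocorticoid receptor that fell by 0.65 (SE 0.18). Adjusted over the list alone 7 fell. Their median log2 difference was -0.44 (camera adjusted p = 2.5e-06), and the call was lost with an estimated correlation (adjusted p = 0.0634). The call for Fkbp5 itself (adjusted p = 0.0488, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) was lost on leaving out any of 34 of the 48 libraries, most of all KO ZT16 replicate 3 (adjusted p = 0.0915).

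**Figure D2:**
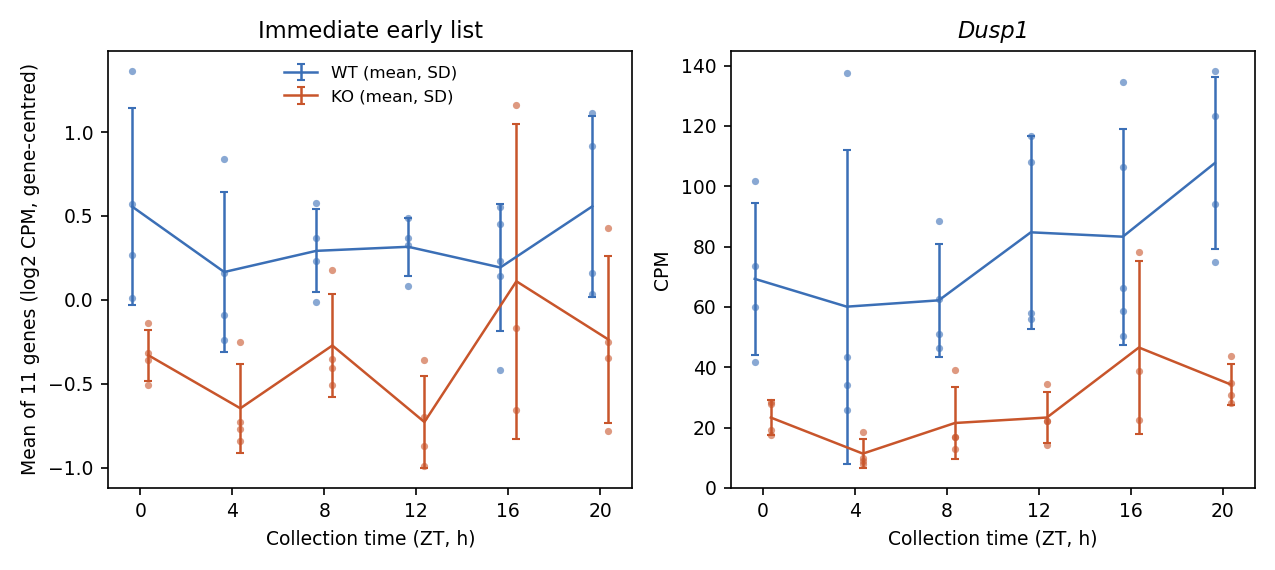
Mean of the 11 immediate early genes per mouse (log2 CPM, gene-centred, left) and Dusp1 in CPM (right) by collection time in WT and KO; small points are mice, lines join group means and bars are SD. Mean Dusp1 in KO was below the WT mean at each of the 6 times.

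Of the gluconeogenesis genes, which make glucose during fasting, a pair fell in KO: Sds, which degrades serine, fell by 0.80 on the log2 scale (SE 0.19), from 265 ± 115 to 153 ± 99.1 CPM, and Slc25a25, a mitochondrial ATP carrier, fell by 0.67 (SE 0.16). These were 2 of 13 measured members, over all genes and adjusted over the list alone. The list had a median of -0.28 (camera adjusted p = 0.00185; adjusted p = 0.575 with an estimated correlation). Of the cell cycle list 1 of 16 fell by either count, Rrm2, a subunit of ribonucleotide reductase, by 0.91 (SE 0.16), from 6.73 ± 2.91 to 3.42 ± 1.496 CPM. The list median was -0.17 (camera adjusted p = 0.00783; adjusted p = 0.465 with an estimated correlation). The call for cell cycle was lost on leaving out 2 of the 48 libraries, and that for Slc25a25 without KO ZT16 replicate 3 (adjusted p = 0.0630, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Sds, Slc25a25, Rrm2, Fkbp5 and Zfp36 no longer passed with body weight as a covariate. In the permutation test of list means, neither gluconeogenesis nor cell cycle passed (Benjamini-Hochberg adjusted p = 0.113 for each).

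PPARalpha targets, cholesterol genes and female-biased liver genes passed camera as lists higher in KO, and each lost its call with an estimated correlation. None of them passed the permutation test of list means (Benjamini-Hochberg adjusted p = 0.450, 0.450 and 0.158, in that order). Over 100 splits of the mice within times, the real one included, camera passed a median of 6 lists. PPARalpha targets had 1 of 28 members past the threshold by either count, Vnn1, a pantetheinase, which rose by 0.68 on the log2 scale (SE 0.16), from 243 ± 88.2 to 386 ± 140 CPM. The list median was 0.09 (camera adjusted p = 0.0130; adjusted p = 0.772 with an estimated correlation). Cholesterol synthesis and uptake had 0 of 23 members past the threshold by edgeR over all genes or adjusted over the list alone, and a median of 0.09 (camera adjusted p = 0.0432; adjusted p = 0.789 with an estimated correlation). Its member with the smallest p, Sc4mol (also called Msmo1), an enzyme of sterol synthesis, had a log2 difference of 0.59 (SE 0.24, adjusted p = 0.202, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Female-biased liver genes had 0 of 14 past the threshold by edgeR over all genes and 4 higher adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00501; adjusted p = 0.465 with an estimated correlation). The smallest p was that of Cyp2b9 (0.25, SE 0.07). With body weight as a covariate the PPARalpha and cholesterol lists no longer passed (adjusted p = 0.852, with the direction turned, and 0.998). On leaving out each library the cholesterol call was lost for 23 of 48 and the PPARalpha call for 5.

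No other gene group passed camera, and the member with the smallest p is given for each. Core clock genes (24 measured) had 1 higher, Npas2, and 2 lower, Gm129 and Bhlhe40 (-0.65, SE 0.16), and adjusted over the list alone 1 higher and 3 lower (camera adjusted p = 0.136; adjusted p = 0.763 with an estimated correlation; 0.0331, lower, without the 7 libraries of extreme GC slope). Lipid droplet and steatosis genes (16) had 1 higher, Cd36 (0.74, SE 0.14, mm9 chromosome 5, 17287508 to 17394777), and 2 higher and 1 lower adjusted over the list alone (0.430). Insulin and growth hormone responsive genes (14) had 1 higher, Irs1 (0.38, SE 0.08), and 1 higher and 1 lower adjusted over the list alone (0.695). The groups with 0 members past the threshold by edgeR over all genes were fatty acid and triglyceride synthesis (22 measured, Scd2 -0.43, camera adjusted p = 0.976), glycolysis and glycogen (18, Pfkfb3 -0.33, 0.368), bile acid synthesis and transport (17, Hsd3b7 0.25, 0.165) and xenobiotic metabolism (23, Cyp2b10 -0.70, 0.83). The same held for male-biased liver (11, Cyp7b1 0.31, 0.71, with a median below 0 and a test above), acute phase (22, Socs3 -0.52, 0.136), unfolded protein and integrated stress response (20, Ppp1r15a -0.51, 0.196), heat shock and temperature responsive (13, Hspd1 0.22, 0.0941) and NRF2 and oxidative stress (11, Nfe2l2 0.11, 0.976). Adjusted over the list alone, 5 heat shock genes were higher and 1 lower, 2 bile acid genes and 1 male-biased gene were higher, 1 fatty acid gene was higher and 1 lower, and 1 unfolded protein gene was lower.

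Of the marker lists of cell types fixed beforehand, none passed camera with the count filter and all libraries. Neutrophil markers (9 measured, Ltf -3.37) had 0 members past the threshold by edgeR but 9 below 0, with a median log2 difference of -1.55 (camera adjusted p = 0.136; adjusted p = 0.789 with an estimated correlation). Camera called them lower without the filter (adjusted p = 0.0380) and without the 7 libraries of extreme GC slope (adjusted p = 0.0163). They did not pass the permutation test of list means (Benjamini-Hochberg adjusted p = 0.450). Lox, which cross-links collagen, rose in KO by 1.34 on the log2 scale (SE 0.27), from 0.245 to 0.613 CPM, as the only 1 of 11 stellate cell and fibroblast markers to pass (camera adjusted p = 0.846). Kupffer cell and macrophage markers (15 measured, Gpnmb -1.10, camera adjusted p = 0.430), T, NK and B lymphocyte markers (15, Cd3e -0.75, 0.258) and sinusoidal endothelium markers (10, Stab1 -0.31, 0.695) had 0 members past the threshold by edgeR. So had cholangiocyte (6, Krt7 -0.49, 0.258), erythroid (5, Hbb-b2 0.45, 0.430) and hepatocyte markers (9, Ass1 -0.43, 0.194). Adjusted over the list alone, 1 stellate cell and fibroblast marker was higher and 1 lower, 2 cholangiocyte markers were lower and 2 adipocyte markers higher. Adipocyte markers, of which 3 of 8 were measured, had a median log2 difference of 0.49 (Lpl, camera adjusted p = 0.0760), and passed the permutation test of list means (Benjamini-Hochberg adjusted p = 0.0351), an alternative chosen after seeing the data. Only 2 of 15 exocrine pancreas genes were measured with the filter, too few for camera, Cela1 at 0.52 (SE 0.18) and Cela2a at 1.23 (SE 0.53), and both were higher adjusted over the list alone. Without the filter camera, at its preset correlation, called the list higher (adjusted p = 8.9e-07). Most members added by this step had too few counts to pass the filter, so the call rests on values near the floor. Whether it came from a few libraries was not tested.

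At single times few genes passed. At ZT0, Star, which carries cholesterol into mitochondria, fell by 2.59 on the log2 scale in KO (SE 0.49), and Cela2a, a pancreatic elastase gene chosen after its values were seen, rose by 6.09 (SE 1.08). At ZT4, Rec8 fell by 2.59 (SE 0.51), Dusp1 by 2.4 (SE 0.44) and the kinase gene Map4k4 by 1.09 (SE 0.22). Tmem171 fell by 5.85 (SE 1.18) and Wfikkn1 by 2.74 (SE 0.56), both chosen after their values were seen. Cela2a, Tmem171 and Wfikkn1 had a mean log2 CPM below 0, under the limit of the naming rule, so their folds rest on low levels. At ZT16, Slc4a9, an anion exchanger, rose by 3.56 (SE 0.70), Pxdn, a peroxidase of the extracellular matrix, by 0.98 (SE 0.18), and the transcription factor gene Foxp1 by 0.95 (SE 0.19). At ZT8, ZT12 and ZT20 the edgeR quasi-likelihood test called 0 genes, with 248, 599 and 249 genes at an unadjusted p under 0.05, while DESeq2 called 2, 3 and 0 and limma voom 0 at each. In simulated counts, which lacked the GC content trend of the libraries, 53% of genes changed by 1 on the log2 scale at ZT8 were recovered.

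The calls at single times rested on few libraries. Star reached 26.5 CPM in WT ZT0 replicate 3 and 2.52 to 3.18 CPM in the other WT mice at ZT0, and without that library 0 genes passed at ZT0 (755 at an unadjusted p under 0.05 with it). The ZT0 count was 6, 7 and 9 without WT ZT0 replicates 1, 2 and 4 and 1 without KO ZT0 replicate 1, 3 or 4, and the ZT12 count 1 and 2 without WT ZT12 replicates 1 and 2. Slc4a9 reached 17.5 CPM in KO ZT16 replicate 2, and without it the log2 difference was -0.22, and that of Foxp1 0.36. No gene then passed at ZT16, nor without WT ZT16 replicates 1, 2, 4 or 5, while 25 and 8 passed without KO ZT16 replicates 1 and 3 and 1 without WT ZT16 replicate 3. At ZT4, 3176 genes had an unadjusted p under 0.05, 3354 passed without KO ZT4 replicate 1, 1 without WT ZT4 replicate 1, and 0 without WT ZT4 replicate 2 or KO ZT4 replicates 2, 3 or 4. The log2 difference of Dusp1 at ZT4 was -1.59 without WT ZT4 replicate 2. Mean GC slopes at ZT4 were 0.21 in WT and -0.33 in KO. With body weight as a covariate Star, Rec8 and Map4k4 and the 3 genes at ZT16 no longer passed. DESeq2 called 10, 193 and 17 genes at ZT0, ZT4 and ZT16, and limma voom 0, 0 and 1. With the replicate number as a block 0 genes passed at each of these times.

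The next question was whether the genotype difference varied with time. Npas2 (mm9 chromosome 1, 39250576 to 39420079) was the 1 gene that passed (interaction, adjusted p = 0.0301, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its deep trough in WT was shallower in KO: WT levels were 0.0742 ± 0.0642 CPM at ZT8, 0.0995 ± 0.0757 at ZT12 and 0.310 ± 0.215 at ZT16, where KO had 1.38 ± 0.207, 1.1 ± 0.443 and 2.34 ± 1.08 (SD, n = 4, n = 5 for WT and n = 3 for KO at ZT16). At ZT0 the levels were 10.5 ± 2.57 CPM in WT and 17.3 ± 4.33 in KO, and at ZT4 6.15 ± 5.66 and 2.53 ± 1.52. The WT counts at ZT8 and ZT12 were 0 to 2 reads per library, so the fold at the trough is known only roughly. The call was lost on leaving out any of 16 of the 48 libraries, most of all KO ZT4 replicate 4 (adjusted p = 0.123, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and with limma voom, which called 0 genes; 448 genes had an unadjusted p under 0.05, and DESeq2 called 7. The count was 3 without KO ZT16 replicate 3 or WT ZT4 replicate 1. It was 2 without KO ZT16 replicate 1, WT ZT12 replicate 2 or WT ZT16 replicate 3. With the replicate number as a block 0 genes passed. Of 100 splits with genotype labels exchanged within times, the real one included, 16 gave at least 1 gene, so chance was not excluded.

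**Figure D3:**
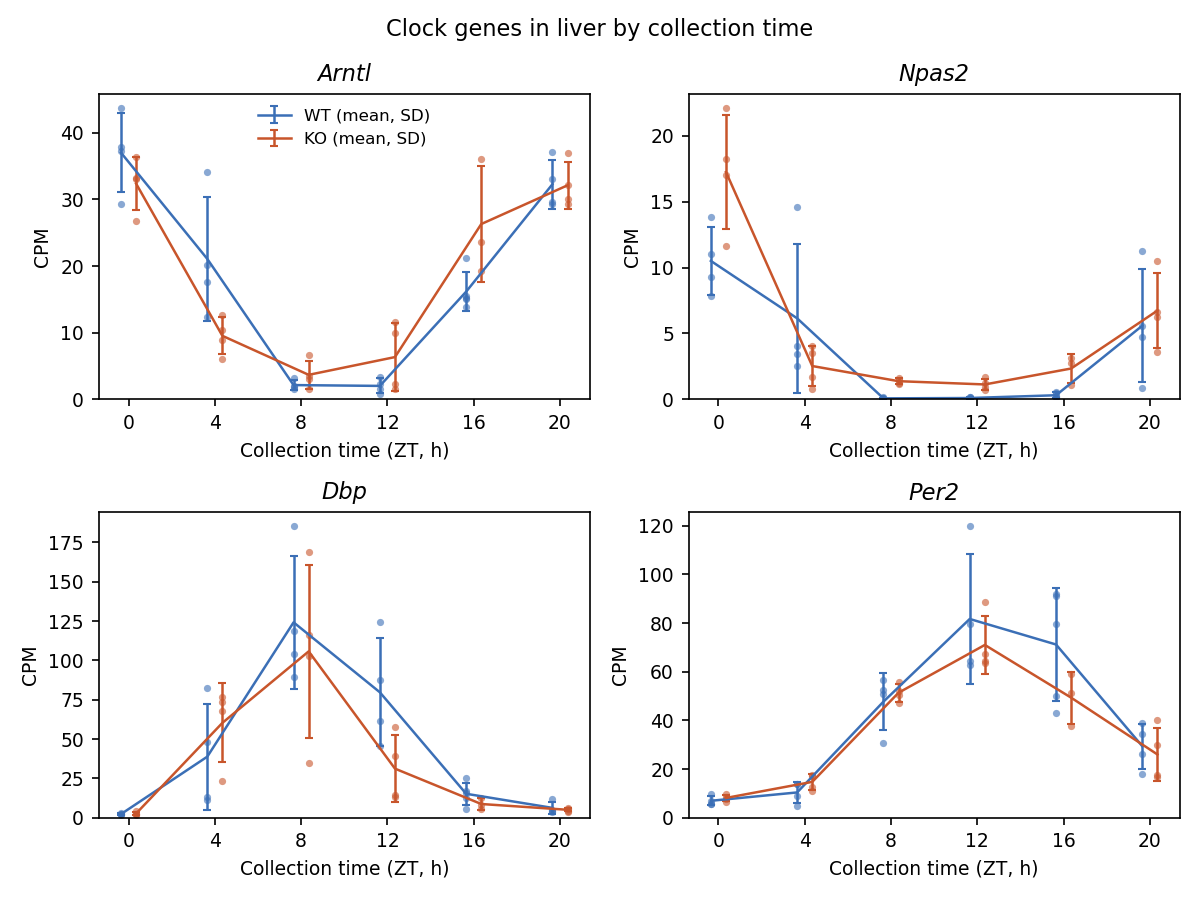
CPM of Arntl, Npas2, Dbp and Per2 by collection time in WT and KO; small points are mice, lines join group means and bars are SD. Npas2 fell to 0.0742 CPM in WT at ZT8 and to 1.1 CPM in KO at ZT12.

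Sampling around the day also asked which transcripts had a 24 h rhythm in each genotype. The clock ran in both: Dbp, a clock-driven transcription factor gene, had an amplitude of 2.69 on the log2 scale in WT (SE 0.28) and 2.38 in KO (SE 0.28), Per3 2.23 (SE 0.19) and 2.38 (SE 0.19), and Cry1, a repressor of the clock, 1.42 (SE 0.10) and 1.41 (SE 0.10). Of 24 core clock genes, 16 were rhythmic in WT and 17 in KO, 16 of them in both (Fisher's exact test for enrichment, adjusted p = 6.9e-07 and 2.4e-07). Clock, Cry2, Rora, Bhlhe40, Csnk1d and Csnk1e were among those that passed in neither, and Per1 passed in KO alone, which does not show a difference between genotypes (difference in rhythm, adjusted p = 1.00, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The Per1 call in KO was lost with body weight as a covariate and on leaving out any of 13 of the 48 libraries, most of all KO ZT16 replicate 2 (adjusted p = 0.110, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Besides clock genes, the widest WT rhythms among genes with a mean log2 CPM of at least 2 were those of Cyp2b10, Cdkn1a and Lpin1. Cyp2b10, a drug-metabolising enzyme, had an amplitude of 2.15 (SE 0.28, peak at ZT 20.2). The cell cycle inhibitor gene Cdkn1a had 1.94 (SE 0.28, ZT 20.3) and Lpin1, of glycerolipid synthesis, 1.86 (SE 0.28, ZT 14.2). In all, 2227 genes (16.3%) were rhythmic in WT and 2321 (17%) in KO, 1308 of them in both, where independent lists would share 379. Mean weight varied with collection time, in KO from 27.95 g at ZT8 to 20.15 g at ZT20 and in WT from 24.0 g at ZT4 to 20.1 g at ZT12. Age varied too, and these fits held neither. With body weight as a covariate 2199 genes passed in WT, 1926 of them among those above, and 2641 in KO, 1916 among those above.

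Rhythmic genes gathered in some lists. Cholesterol synthesis and uptake had 16 of 23 members rhythmic in WT (Fisher's exact test, adjusted p = 5.4e-07) and 7 in KO (0.226), and heat shock and temperature responsive genes 11 of 13 in WT (1.2e-06) and 6 in KO (0.0578). Glycolysis and glycogen genes had 9 of 18 in WT (0.00696) and 10 in KO (0.00167). In KO, neutrophil markers had 8 of 9 (adjusted p = 7.7e-05, Fisher's exact test; 1 in WT), sinusoidal endothelium markers 8 of 10 (0.000218; 3 in WT), glucocorticoid responsive genes 8 of 13 (0.00230; 6 in WT) and insulin and growth hormone responsive genes 8 of 14 (0.00380; 3 in WT). Fisher's exact test takes genes as independent, but members of a list can move together. The estimated correlation between members ran from 0.040 for glycolysis and glycogen to 0.824 for neutrophil markers, with 0.556 for cholesterol genes. These p-values therefore overstate the evidence, most of all for the highly correlated lists. Whether these lists differed between genotypes was not tested. The most frequent peak was within the 4 h around ZT0 in WT (21.4% of its rhythmic genes) and around ZT20 in KO (26.8%). These shares come from different, partly shared sets of genes and were not tested against each other. Over the genes rhythmic in the shared fit the median KO minus WT peak difference was -0.626 h. Of 100 exchanges of genotype labels 35 lay as far from 0. With collection time as a factor, 1165 genes passed in WT and 1329 in KO, and without KO ZT16 replicate 3, 3721 passed in KO.

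The rhythm itself differed between genotypes for 1 gene, Mpzl1, which encodes a membrane glycoprotein (mm9 chromosome 1, 167522312 to 167564672). Its amplitude was 1.54 (SE 0.12) in WT and 0.75 (SE 0.12) in KO, with peaks at ZT 23.3 and ZT 20.7 (adjusted p = 0.00491, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and it passed on leaving out each of the 48 libraries. Its mean level fell from 16.5 ± 6.35 CPM at ZT0 to 1.65 ± 0.602 at ZT12 in WT, and from 9.60 ± 1.67 to 4.34 ± 0.889 in KO (SD, n = 4). DESeq2 called 5 genes, and 365 had an unadjusted p under 0.05. With time as a factor, which repeats the interaction test above, Mpzl1 no longer passed. With the replicate number as a block 0 genes passed. Of 100 splits with genotype labels exchanged within times, the real one included, 24 gave at least 1 gene, so chance was not excluded. Without WT ZT16 replicate 2 or WT ZT4 replicate 1 the count was 2.

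Clock genes peaked earlier in KO as a set. Of the 16 rhythmic in both genotypes, 15 had an earlier fitted peak in KO, by a median of -0.923 h (range -2.25 h for Bhlhe41 to 0.439 h for Fbxl21). Arntl peaked at ZT 22.2 in WT and ZT 20.9 in KO (SE 0.324 and 0.454 h), Dbp at ZT 9.63 and ZT 8.23 (SE 0.381 and 0.465 h), Per2 at ZT 13.3 and ZT 12.5 (SE 0.284 and 0.361 h) and Cry1 at ZT 18.98 and ZT 18.1 (SE 0.268 and 0.277 h). In 0 of 100 exchanges of genotype labels within times was the median as far from 0, the farthest being 0.858 h. None of the 16 passed the test of a difference in rhythm alone. Over all 2780 genes rhythmic in the fit shared by both genotypes, the median difference in peak was -0.626 h and 66.8% peaked earlier in KO. In peak time 35 of 100 exchanges lay as far from 0. The median log2 ratio of KO to WT amplitude over these genes was 0.06, and 69 of 100 exchanges lay as far from 0 (range -0.53 to 0.46), so no general change of amplitude was detectable.

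**Figure D4:**
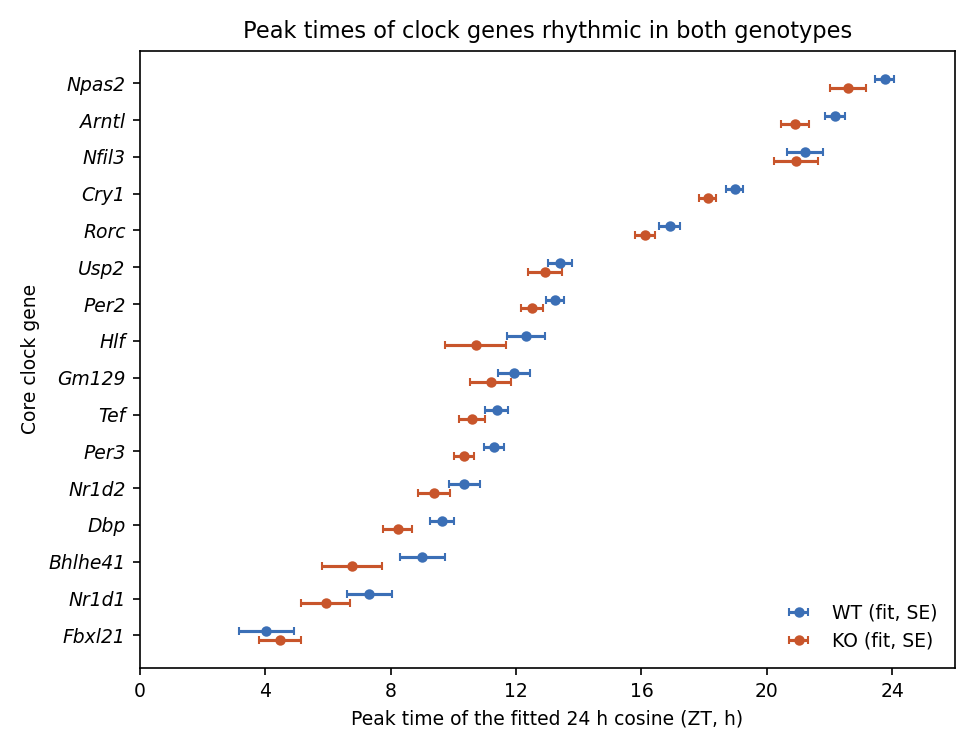
Peak time in hours (ZT) of the fitted 24 h cosine for the 16 core clock genes rhythmic in both genotypes; points are estimates in WT and KO and bars are SE. The KO point lies to the left of the WT point for 15 genes.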

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

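The tests of GC content, of a few libraries and of cell types for the immediate early genes were chosen after that result was seen, that of neutrophils and portal fibroblasts after their medians were known, and the test of the other cell types was changed once its first version (the highest median log2 difference among 5 lists of such cells, 0.02) was known; the remaining tests were chosen beforehand. Values far from the rest of their group were looked for in 66 groups of 4 or 5 mice and found in 9. The test's chance rate of about 1 in 20 assumes normally distributed values. It was run on CPM, in part for genes chosen because they were called at that time, so the 9 cannot be set against that rate. KO ZT8 replicate 2 weighed 34.5 g, where the other mice of its group weighed 25.5 to 26 g. Arntl was 21.3 CPM (21.25) in WT ZT16 replicate 2 and 13.8 to 15.4 CPM in the others. WT ZT4 replicate 2 stood apart in Npas2, with 14.6 CPM (14.59) against 2.54 to 4.02, and in Dusp1, with 137 CPM (137.4) against 25.7 to 43.2. Mpzl1 was 2.01 CPM (2.009) in WT ZT8 replicate 1 against 2.58 to 2.61, and 0.749 CPM in WT ZT12 replicate 3 against 1.87 to 2.05. Fos was 2.1 CPM in KO ZT20 replicate 1 against 0.461 to 0.676. Star was 26.5 CPM (26.47) in WT ZT0 replicate 3 against 2.52 to 3.18. Map4k4 was 15.2 CPM (15.19) in KO ZT4 replicate 1 against 10.4 to 10.9. The genotype difference of Npas2 varied between collection times (adjusted p = 0.0301, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and the rhythm of Mpzl1 differed between genotypes (adjusted p = 0.00491, same test).

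Leaving out KO ZT4 replicate 1 raised the number of genes called at ZT4 from 5 to 3354, of which 1657 were higher in KO with a median GC content of 42.99% and 1697 lower with a median of 55.0%. Collection of this mouse at another time was argued against by its clock genes, which lay nearest to those of ZT4 (distance 0.66 log2 units, next nearest time 1.38), with 0 times nearer. With the GC content trend of each library removed, 1651 genes were called without it, 1214 of them also called before, which lay between the bounds set beforehand for and against this explanation. The share of the calls that came from GC content therefore cannot be told apart from a difference between genotypes at ZT4, since KO ZT4 replicates 3 and 4 had slopes of -0.80 and -0.68. Library construction day, which the labels do not give for each library, and genotype stay open.

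Immediate early genes were lower in KO with a median log2 difference of -0.82 (-0.69, or -0.691, with the GC content trend removed), and exchanging genotype labels within times gave a permutation p of 2e-05 (100000 draws, two-sided). The median KO mouse was lower than the median WT mouse at 6 of 6 times, which argues against a few libraries, though at ZT16 the mean differed by only -0.08 and KO ZT16 replicate 2 (1.16 above the average of all mice, log2) was higher than each WT mouse but WT ZT0 replicate 1. A lower share of Kupffer cells, lymphocytes, stellate cells, endothelium and cholangiocytes alike was argued against by their 57 markers (median -0.0722, SD 0.326). Neutrophil markers (median -1.55, 9 of 9 below 0) and portal fibroblast markers (median -0.52) were lower. Their joint median was -0.711 over 19 markers (SD 0.994). The neutrophil list did not pass the permutation test of list means (Benjamini-Hochberg adjusted p = 0.450), and its members were correlated (0.824). The portal fibroblast list was written after called genes had been seen, so it is not independent of the result. With body weight as a covariate the immediate early list still passed (camera, Benjamini-Hochberg adjusted p = 7.5e-08, and at most 0.0474 over all alternatives). A lower share of these cells, the order of handling at collection, the library day and an effect of the knockout through signals to the liver stay open, and the last is a hypothesis that these data may motivate but do not test.

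Clock genes peaked earlier in KO by a median of -0.923 h. Chance differences between mice were argued against by 0 of 100 exchanges of genotype labels as far from 0 (farthest 0.858 h). The difference was -0.944 h with the GC content trend removed, which argues against that trend as the cause. With age in the fit it was -0.991 h. Mean age was the same in both genotypes at each time but ZT16, so that fit could hardly have moved the difference. Collection order and library day stay open, and so does body weight, which was not put into this fit. An advance of the liver clock after loss of Bmal1 in adipocytes is a candidate explanation, as a hypothesis found and tested on the same mice, which were sampled every 4 h.

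Other splits of the mice within times showed how often chance gave results as large. For all times, 2 of 100 splits, the real one included, gave at least 193 genes, so chance alone is unlikely, but the highest other split gave 2327 genes, which points to a structure of the samples. Rhythmic genes were as many in 1 of 100 random orders of collection times in WT (2227, highest other 1072) and 1 of 100 in KO (2321, highest other 112). That was the real order in both cases, so chance alone is unlikely, though with 100 orders the share cannot fall lower. Chance was not excluded for the interaction (1 gene, 16 of 100, highest other 11), the difference in rhythm (1 gene, 24 of 100, highest other 11) or the number of lists passing camera (7 lists, 42 of 100, highest other 13, median 6). Nor was it at ZT0 (2 genes, 2 of 35, highest other 15), ZT4 (5 genes, 3 of 35, highest other 2690) or ZT16 (3 genes, 27 of 56, highest other 1870). At ZT8, ZT12 and ZT20 the real count was 0, which each of the 35 splits reaches whatever the data, so the splits say nothing about chance there (highest other 0, 2 and 0). Splits at ZT4 and ZT16 that called many times the real count point to a structure of the samples there as well.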

How the results depend on the processing

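Alb kept, the GC trend removed, leaving out 7 libraries of extreme GC slope (beyond 0.6) and the permutation of list means were chosen after seeing the data. The limit of 0.6 was chosen after the slopes were seen, and 0.5 was dropped as it left too few KO ZT4 libraries. Counts with the GC trend removed were known when it was added. Of 119 values for named genes and lists, 118 kept direction and call with DESeq2's size factors, 115 with Alb kept, 112 with age, 110 without filter, 106 with the GC trend removed, 105 without the 7 libraries and 89 with body weight, the rest losing or gaining a call or turning direction; of the 112 gene values (lists not run), 104 did with DESeq2, the other 8 gaining a call, and 103 with limma voom; the cause was not tested. Counts that moved by over 1.5 times are given next. For all times (193): 122 without filter, 354 with DESeq2, 37 with body weight (9 higher, 28 lower), and the split was 67 to 105 with DESeq2's size factors. For ZT0 (2): 5 with DESeq2's size factors, 10 without filter, 10 with DESeq2, 0 with limma voom, 1 with weight, 5 with Alb kept, 7 with the GC trend removed. For ZT4 (5): 2 without filter, 193 with DESeq2, 0 with limma voom, 1 with weight, 0 without the 7 libraries. For ZT8 (0): 2 with DESeq2. For ZT12 (0): 1 without filter, 3 with DESeq2, 1 with age, 1 with weight, 1 without the 7 libraries. For ZT16 (3): 0 without filter, 17 with DESeq2, 1 with limma voom, 0 with age, with weight and with Alb kept, 15 without the 7 libraries. For the interaction (1): 7 with DESeq2, 0 with limma voom. For rhythm, collection time as a factor gave 1165 in WT and 1329 in KO, leaving out the 7 libraries 3676 in WT, and DESeq2 5 genes for the difference. For the difference, time as a factor is the same test as the interaction, and its 1 gene was Npas2, not Mpzl1. Lists passing (7): 1 with an estimated correlation, 2 with fry, 3 with the permutation of list means (immediate early 0.00056, glucocorticoid responsive 0.00154 and adipocyte 0.0351, Benjamini-Hochberg adjusted p; 2 shared with camera). The PPARalpha list turned direction with weight (adjusted p = 0.852), and the amplitude ratio turned to -0.013 with the GC trend removed and -0.067 without the 7 libraries. Leaving out each library gave 101 to 476 genes over all times, 0 to 9 at ZT0, 0 to 3354 at ZT4, 0 at ZT8 and ZT20, 0 to 2 at ZT12, 0 to 25 at ZT16, 0 to 3 for the interaction, 1874 to 2985 rhythmic in WT, 1629 to 3721 in KO, 1 to 2 for the difference, an amplitude ratio of -0.039 to 0.20 (below 0 without WT ZT20 replicate 2, KO ZT20 replicate 1 or WT ZT12 replicate 3) and 4 to 10 lists. Slc4a9 at ZT16 ranged from -0.22 (without KO ZT16 replicate 2) to 4.16. The labels do not say what a replicate number marks, and whether it pairs the mice stays open: of 23 pairs, 22 of the same age, 13 had a correlation over 0.1 (median 0.119, -0.388 to 0.489), and 10 WT libraries correlated best with their own number. With the replicate block, which also left out 2 unpaired WT ZT16 libraries (46 kept), 123 genes passed over all times (39 higher, 84 lower, 103 shared), 0 at ZT0, ZT4 and ZT16, 0 for the interaction (Npas2, adjusted p = 0.405, edgeR with Benjamini-Hochberg) and 0 for the difference in rhythm (Mpzl1, 0.265); 50 named values kept direction and call, 17 no longer passed and 1 newly passed. With it 8 lists passed, neutrophil (0.00166) being new. The amplitude ratio could not be fitted with a block and was 0.066 on the 46 libraries. Depth limits Npas2 at its WT trough, Fos and Rec8.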

Other observations

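Some interferon-induced genes rose in KO. The list for this group, and those for portal fibroblasts, mesothelium, ribosome and respiratory chain, were written after the called genes (such as Gbp10, Podn and Serpine2) had been seen, so they are not independent of the result. Of 24 interferon genes tested, 4 rose over all genes: Ifit1, which blocks viral RNA, by 0.79 on the log2 scale (SE 0.17), Gbp3 by 0.65 (SE 0.18), Isg15, a ubiquitin-like protein, by 0.52 (SE 0.14) and Usp18, which removes it, by 0.50 (SE 0.11). The list's median was 0.36 (camera adjusted p = 2.5e-11, Benjamini-Hochberg over 5 lists; adjusted p = 0.0645 with an estimated correlation; permutation test of list means, adjusted p = 0.00513). Gbp genes form a multigene family and the counting of reads that match several copies is not stated, so the values of single members are uncertain.

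Of 10 portal fibroblast genes tested, 2 fell in KO: Fbln1 by 0.91 on the log2 scale (SE 0.24) and Fbln2 by 0.72 (SE 0.18), both matrix proteins, and the list's median was -0.52 (camera adjusted p = 3.5e-06; adjusted p = 0.0384 with an estimated correlation; permutation adjusted p = 0.00165). Genes of the mesothelium (8 tested, camera adjusted p = 0.0888), the cytosolic ribosome (73, 0.0888) and the mitochondrial respiratory chain (77, 0.213) did not pass camera. Ribosome genes did with the GC content trend removed (camera adjusted p = 0.0191, 0 of 73 members past the threshold by edgeR), but without that correction had an adjusted p = 0.748 with an estimated correlation and 0.695 in the permutation test of list means.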
